A study of Drosophila melanogaster with 6 samples.

How the data were processed

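RNA from the central brain of Drosophila melanogaster was measured on 6 single-colour Agilent arrays, 3 of control animals and 3 of DIP2 knockdown animals, per the labels. Controls carried the OK107-Gal4 driver, which is active in the mushroom bodies, with UAS-dicer2. Knockdown animals also carried a UAS-DIP2-RNAi transgene. All animals were raised at 29 °C and labelled female, and the 3 samples of a group were described as biological replicates. The stage was given as white pupa in most labels and as 24 hours after puparium formation in another, and this conflict was left open.

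Spot intensity values were made by the authors with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The processed signal was background-subtracted and detrended within each array, and not scaled between arrays, per the file headers. Other deposited values were flags for outlier, saturated and well-above-background spots. A deposited set of log2 values of the same spots was used as an alternative. Its scale was found from the values to be log2 and not centred per gene, with medians of 7.02 to 7.03 on the 6 arrays and correlations across spots of 0.966 to 0.984 with the log2 processed signal. How the authors normalized those log2 values was not given in the sources used here. Probe positions followed the dm3 build, per the file headers.

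The processed signal of 43602 non-control spots was taken to log2, and each array's 75th percentile was subtracted. Spots marked as outliers were left out, and the spots of each of 32162 probes were averaged. Probes flagged well above background on all 3 arrays of at least 1 group were kept, which left 19622. The brightest probe over all 6 arrays, chosen without regard to group, stood for its gene. This gave 13814 entries, of which 9329 had a gene name and 4485 were cDNA clones, assembled transcripts or probes without one. A current symbol was found for 9095 entries in a RefSeq gene table of Release 6, used for names only, and 234 kept the name in the array's files.

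Groups were compared with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are DIP2 knockdown minus control on the log2 scale, and each SE is the moderated one of limma. Where a probe was not well above background on any array of one group, a bound was computed as the bright group's mean against the mean, per array, of the higher of the lowest well-above-background signal and the probe's own value. Such a bound, written as "at least", holds at the main setting only. In total, 24 fixed gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. The text names DIP2 and gkt, the 10 largest rises and 10 largest falls among named genes past the threshold with non-overlapping groups (filled to 10 by p among genes changed by at least 0.5), and up to 3 members with the lowest p of each list described. Which lists were described gene by gene was narrowed to 12 after their values were seen, and the others have a median only. List members named for passing without DIP2 knockdown replicate 2 were also chosen after their values were seen. For lists of other cell types, the 2 brightest members were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

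The fit and threshold were tested on simulated log2 values with genes changed by known amounts among 13754, with the real means and residual spread. Noise was normal, independent between genes and of equal spread on every array. Background, scaling, filter and probe choice were not simulated, nor was an array that stands apart or correlation between genes. The shares and false calls below therefore describe that simpler setting and not these arrays. With all 6 arrays, 28% of genes changed by 1 and 67% of genes changed by 2 on the log2 scale were called, with 2 false calls. On the 5 arrays without DIP2 knockdown replicate 2, the shares were 52% and 81%, with 4 false calls.

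Signal strength differed between arrays. The 75th percentile of the processed signal ran from 778 to 1459, between 61.2% and 74.8% of spots were well above background, and no spot was saturated. The number of arrays limits the precision. The header of each file placed replicates 1 and 2 of both groups on one slide (4 arrays) and replicate 3 of both on another (2 arrays), so the slide was tested as a block.

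The gene lists and these alternatives were fixed before the data were examined: other scalings, normexp background correction, other filters, other ways of joining probes, kept outlier spots, another eBayes prior, the replicate number or the slide as a block, the deposited table, a looser threshold and leaving out each array. Array weights, and the slide block without DIP2 knockdown replicate 2, were chosen after seeing the data. That array stood apart, and its group was not changed.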

Results

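The expression of central brain RNA was measured in 3 control and 3 DIP2 knockdown samples, to ask which genes change when DIP2 is lowered by RNA interference in the mushroom bodies. The series title sets this beside axonal bifurcation of the mushroom body and names glaikit (gkt). DIP2 is disco-interacting protein 2, a protein with domains related to acyl-CoA synthetases. The OK107-Gal4 driver is active in only part of the brain, and RNA was taken from the whole of the central brain. Control arrays correlated with each other at 0.989 to 0.992 across entries. DIP2 knockdown replicates 1 and 3 correlated at 0.984, and DIP2 knockdown replicate 2 with the other 5 arrays at 0.904 to 0.920. With the controls, DIP2 knockdown replicate 1 correlated at 0.979 to 0.983 and replicate 3 at 0.965 to 0.971. DIP2 knockdown replicate 2 differed by 2-fold or more from the mean of the other 5 arrays at 3216 entries (23.3%). The count was 1506 (10.9%) for DIP2 knockdown replicate 3 and 415 to 616 for the remaining arrays.

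DIP2 signal was lower in knockdown brains by a small margin that did not pass the threshold. Its main probe (3L, 250328 to 250387, dm3) had a mean of 2.28 ± 0.06 in controls and 2.09 ± 0.06 in knockdown (SD, n = 3 each), relative to the array's 75th percentile. The difference was -0.18 (SE 0.13), or 88.0% of control, with an adjusted p of 0.468 in limma. That SE is moderated with the spread of all entries, and it is larger than the SD within either group. All 4 DIP2 probes pointed the same way, from -0.13 to -0.43. For the main probe all 3 knockdown arrays lay below all 3 controls, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows. Groups did not overlap at 31.9% of all entries either, and the median absolute difference of all entries was 0.30, larger than that of DIP2. Median scaling moved all entries up by 0.27 alike, which put DIP2 at 0.083, and relative to the median of all entries DIP2 stood at -0.14 with either scaling. On the first slide the difference was -0.19 and on the second -0.18. The position of the RNAi hairpin in the gene was not given in the sources used here.

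The gkt signal was 55.5% of control, which did not pass the threshold over all entries. Glaikit is a phospholipase D family protein related to tyrosyl-DNA phosphodiesterase. It is named in the series title and may have been chosen on these samples, so its value is not taken as independent evidence. Its main probe (2L, 3162078 to 3162137, dm3) had a mean of 1.30 ± 0.17 in controls and 0.45 ± 0.27 in knockdown (SD, n = 3 each). The difference was -0.85 (SE 0.19), with an adjusted p of 0.115 in limma, and the second probe gave -0.75. Without DIP2 knockdown replicate 2 the difference was -0.95 and the adjusted p in limma 0.035. With the slide as a block the adjusted p in limma was 0.160. Within slides the differences were -0.81 and -0.92.

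**Figure D1:**
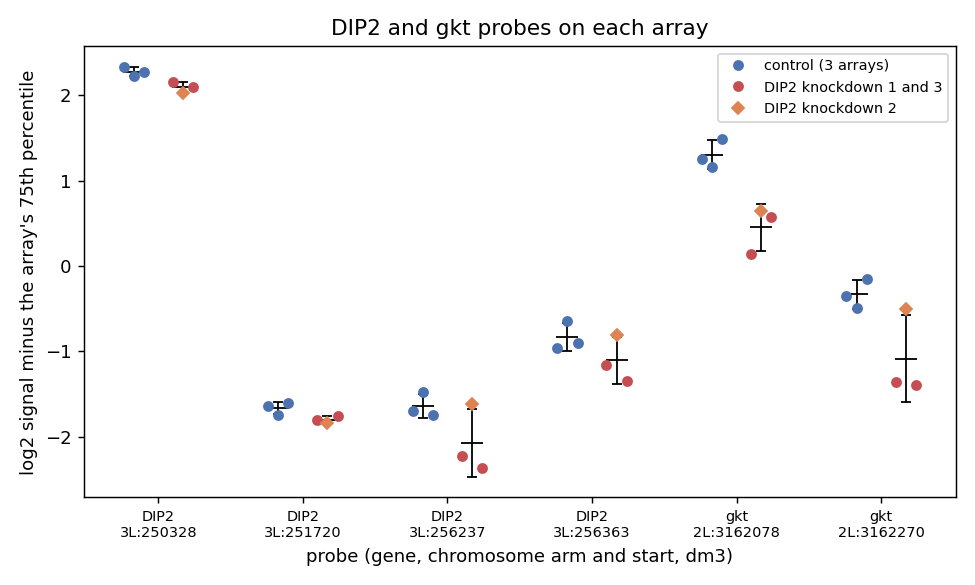
Log2 signal minus the array's 75th percentile for the 4 DIP2 and 2 gkt probes on each of the 6 arrays, with the mean and SD of each group (n = 3). The first gkt probe has a control mean of 1.30 and a knockdown mean of 0.45, while DIP2 probes differ by -0.13 to -0.43.

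Across 13814 entries, 12 rose and 42 fell in DIP2 knockdown brains, and 14 rose and 13 fell with median scaling, which moved all entries up by 0.27 alike. Among those with a gene name, 6 rose and 11 fell, and 37 were clones or transcripts without one. The largest rise among named genes was in Dnaaf3, an assembly factor of axonemal dynein, by 3.58 (SE 0.34), and it was well above background on 1 of 3 control arrays. TpnC4, a troponin C, was not well above background in controls and was at least 2.07-fold higher in knockdown. With normexp background correction Dnaaf3 had 1.65 and TpnC4 0.50, with adjusted p of 0.0879 and 0.473 in limma. Rises of 1.37 in CG8833, 1.35 in the glycolytic enzyme Pfk, 1.33 in the dynactin subunit DCTN5-p25 and 1.13 in the formin dia followed. The other Pfk probes gave 0.35 and 0.39, and the other DCTN5-p25 probe gave -0.04, so the probes of DCTN5-p25 disagreed. With the mean of a gene's probes, Pfk had 0.70 and DCTN5-p25 0.64, and neither passed the threshold (adjusted p 0.126 and 0.0905 in limma). Adjusted p in limma for these rises ran from 0.0237 to 0.0438. The next genes by p did not pass the threshold, namely Lmx1a (1.23), the kinesin Klp68D (1.19), the gustatory receptor Gr28b (at least 2.50-fold higher) and ATPsynepsilonL (0.97). With normexp and quantile normalization Gr28b had a log2 difference of 0.49.

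Among the falls, TTLL15, of the tubulin tyrosine ligase-like family, was at least 9.76-fold lower in knockdown, CG43052 at least 9.37-fold and CG5096 at least 4.91-fold, none being well above background on any knockdown array. Pdh, photoreceptor dehydrogenase, fell by 4.30 (SE 0.29), and CG31955 fell by 2.96. PGRP-SC2, a peptidoglycan-cleaving recognition protein, fell by 2.60 and its second probe by 2.77. ZnT77C, of a zinc transporter family, fell by 2.52, CG2641 fell by 2.12, CG13086 fell by 2.01 and CG4594 fell by 1.62. Gpxl, named after its value was seen, fell by 1.51. Pdh, ZnT77C, CG2641 and CG13086 were well above background on 1 of 3 knockdown arrays, so the sizes of their falls depended on how background was treated. With normexp these 4 had -2.41, -0.83, -0.80 and -0.66, and with the deposited table -3.04, -1.15, -1.12 and -0.98. With normexp TTLL15 had -1.32, CG43052 -1.27, CG5096 -0.71 and CG31955 -1.79, and with the deposited table -1.99, -2.05, -1.17 and -2.14. The bounds for TTLL15, CG43052 and CG5096 thus hold at the main setting only. Of the 16 rises and falls of the naming rule, 5 passed in limma with normexp, 11 with the deposited table, 11 with median scaling and 1 without a filter. Adjusted p in limma for these falls ran from 0.00378 to 0.0382.

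**Figure D2:**
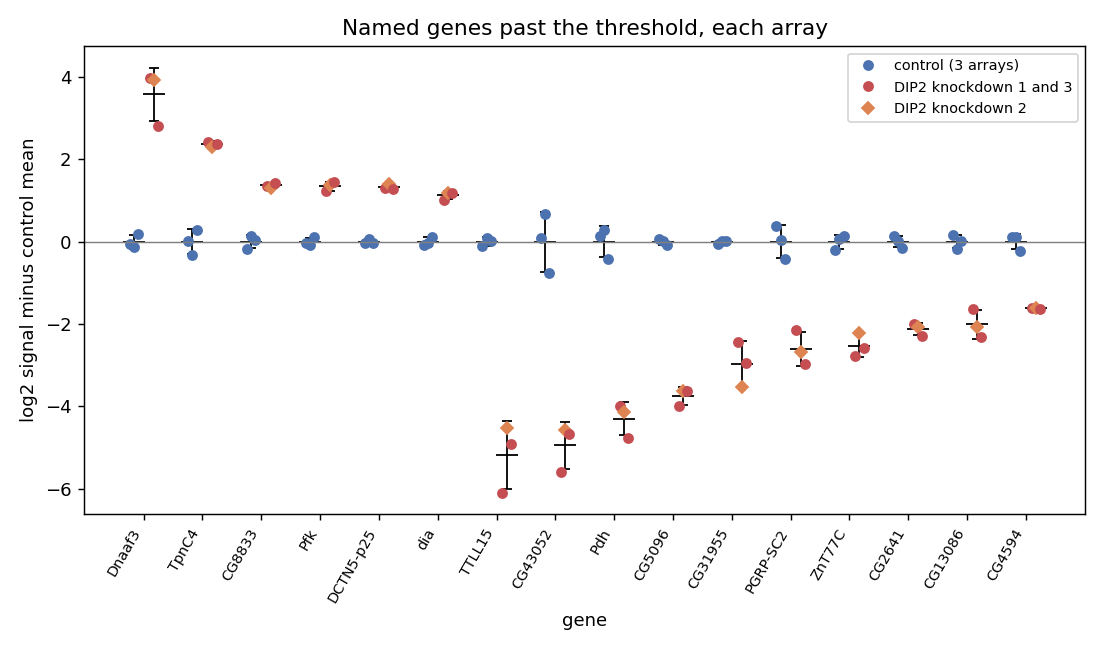
Log2 signal minus the control mean of 16 of the 17 named genes past the threshold, on each array, with the mean and SD of each group (n = 3). Pfk lies 1.35 above and CG4594 1.62 below the control mean on average, signals near background are drawn as measured, and genes were chosen so that the 3 knockdown arrays lie on one side of the 3 controls.

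At an unadjusted p under 0.05 there were 2559 entries, against 691 by chance, and 869 of them changed at least 2-fold (164 higher, 705 lower, against 551 and 334 with median scaling). Groups did not overlap at 4411 entries (31.9%), against 10% by chance. The counts depended on single arrays. Without DIP2 knockdown replicate 2, limma called 319 higher and 1369 lower, including all 54 with their sign, while without any 1 control array it called 0. With the slide as a block it called 0 higher and 3 lower, and with the replicate number as a block 0 and 0. Within the first slide alone limma called 0, with 1221 at an unadjusted p under 0.05.

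Genes of neuropeptides and neurosecretory hormones were higher as a list at the preset correlation, and not with an estimated one. At the preset correlation all 10 splits of the arrays into 3 against 3 gave at least 5 lists, and the real split gave 5. A pass there, for this list or those below, does not by itself set the real groups apart. The median of 38 measured members was 0.52, with a camera adjusted p of 0.00143 in limma and a p of 0.196 with an estimated correlation. None passed the threshold over all entries, and 10 rose and 1 fell when adjusted over the list alone. Dh31, a diuretic hormone, differed by 1.35 (SE 0.22), the ion transport peptide ITP by 1.15 (SE 0.22) and Nplp4, well above background on 1 of 3 knockdown arrays, by -1.97 (SE 0.35; -0.52 with normexp). Without DIP2 knockdown replicate 2, 8 rose and 1 fell over all entries (18 and 4 adjusted over the list alone), and the camera adjusted p in limma was 7.51e-05, with p = 0.241 with an estimated correlation. The list median was 0.41, 0.08 and 0.84 above the control mean on knockdown replicates 1, 2 and 3, and -0.15, -0.10 and 0.26 from it on control replicates 1, 2 and 3, so the groups overlapped. The median was 0.28 without DIP2 knockdown replicate 3, with a camera adjusted p of 0.0240 in limma. On the slides it was 0.35 and 0.64, and with the slide as a block the camera adjusted p in limma was 8.32e-05 (p = 0.0183, adjusted p = 0.440, with an estimated correlation).

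Genes of hemocytes and the basement membrane were lower as a list at the preset correlation, and not with an estimated one. The median of 19 members was -0.59, with a camera adjusted p of 0.00314 in limma and a p of 0.031 (adjusted p 0.694 in limma) with an estimated correlation, and fry gave an adjusted p of 0.0548 in limma. Adjusted over the list alone, 4 fell and 0 rose, and over all entries 0 passed. The collagen IV chains Col4a1 and vkg had differences of -1.1 (SE 0.16) and -1.15 (SE 0.20), and the scavenger receptor Sr-CI one of -2.10 (SE 0.46; -0.92 with normexp and quantile normalization). The brightest members were Fer1HCH (0.28) and trol (-0.49). Within the slides the median was -0.62 and -0.81, and with the slide as a block the camera adjusted p in limma was 0.00561 (p = 0.0625, adjusted p = 0.689, with an estimated correlation). Col4a1, vkg, the laminin LanB2 and SPARC fell over all entries when DIP2 knockdown replicate 2 was left out, and 8 members fell adjusted over the list alone.

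The mature neuron and synapse list had a median of 0.32 over 34 members, with a camera adjusted p of 0.00477 in limma and a p of 0.394 with an estimated correlation. Adjusted over the list alone, 0 rose and 0 fell. Rdl, a GABA receptor, differed by 1.04, the vesicular transporter Vmat by 1.34 and Syt4 by 0.57. The list median was 1.19 above the control mean on DIP2 knockdown replicate 2, against 0.04 and -0.09 on replicates 1 and 3. Without that array it was -0.06, with a camera adjusted p of 0.612 in limma, and 1 member rose and 2 fell over all entries (0 and 1 adjusted over the list alone). It was 0.47 on the first slide and -0.13 on the second, and the camera adjusted p in limma with the slide as a block was 0.00648 (p = 0.412 with an estimated correlation).

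Mushroom body genes had a median of 0.33 over 29 members, with a camera adjusted p of 0.0358 in limma and a p of 0.310 with an estimated correlation. Adjusted over the list alone, 1 rose and 0 fell. The vesicular transporter prt differed by 1.1 (SE 0.20), mamo by -1.68 (SE 0.51; -0.05 for the probe well above background on all 6 arrays) and the octopamine receptor Oamb by 1.06 (SE 0.35). The median was 0.13 without DIP2 knockdown replicate 2, with a camera adjusted p of 0.153 in limma, and the list did not pass without DIP2 knockdown replicate 1 (0.0582) or control replicate 3 (0.0537) either. Nor did it pass with quantile normalization (camera adjusted p 0.0702 in limma), normexp and quantile normalization (0.0823), all probes (0.182) or the deposited table (0.0865). With the mean of a gene's probes the median was 0.15 and the camera adjusted p in limma 0.0793. The list passed in 12 of 22 other settings. In the fit without DIP2 knockdown replicate 2, 3 rose (prt, DAT and sNPF) and 1 fell (scb), both over all entries and adjusted over the list alone. Within slides the median was 0.36 and -0.01, and with the slide as a block the camera adjusted p in limma was 0.0375 (p = 0.314 with an estimated correlation).

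Cuticle and trachea genes had a median of -1.19 over 14 members, with a camera adjusted p of 0.0358 in limma and a p of 0.364 with an estimated correlation. Adjusted over the list alone, 0 rose and 0 fell. Gasp differed by -1.34, Edg91 by -0.91 and kkv, a chitin synthase, by -0.96, while the brightest member, Ccp84Ad, had 0.16 (Gasp being the other). The list lay -2.62 from the control mean on DIP2 knockdown replicate 2, against -0.16 and -0.59 on replicates 1 and 3. Without that array the median was -0.33 and the camera adjusted p in limma 0.124, and 4 of the 14 members fell over all entries (Gasp, Edg91, btl and obst-B), as did 4 adjusted over the list alone. The list did not pass without control replicate 1 (camera adjusted p 0.0563 in limma) or 3 (0.0537) either. Without a filter the median was -0.55 (camera adjusted p 0.141 in limma), and with array weights it was -0.59 (0.200). It passed in 16 of 22 other settings. Within slides the median was -1.38 and -0.66, and with the slide as a block the camera adjusted p in limma was 0.0396 (p = 0.383 with an estimated correlation).

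Other lists did not pass the threshold with all 6 arrays. Axon guidance and adhesion genes had a median of 0.09 over 80 members (camera adjusted p 0.0731 in limma), with the actin regulator ena at 1.11 (SE 0.17), robo3 at 0.51 and the integrin if at -1.26. That median was -0.03 without DIP2 knockdown replicate 2, where it lay 0.25 above the control mean, so this array set its direction, and without it 1 member rose and 3 fell over all entries (1 and 1 adjusted over the list alone). The axon pruning median was 0.01, with put at -0.53, Shark at -0.44 and kat-60L1 at 0.63. Fatty acid and diacylglycerol genes had a median of -0.09, with Baldspot at 0.46, Lpin at 0.43 and Cds at 0.78. For ecdysone response genes the median was -0.25, with MsrA at -0.81, Rbf at 0.45 and crol at -0.41. Neuroblast and cell cycle genes had a median of -0.49, with E2f1 at 0.47, CycD at -0.48 and RnrL at -0.82, and that list lay -1.57 from the control mean on DIP2 knockdown replicate 2, against 0.04 and 0.08 on replicates 1 and 3 (0.09 without that array). The detoxification median was -0.17, with 3 lower and 0 higher adjusted over the list alone, namely GstE9 (-2.95), Cyp6a17 (-2.27) and Cyp6a13 (-1.20). For this list, leaving out DIP2 knockdown replicate 2 gave a median of -0.26, with 10 lower and 4 higher adjusted over the list alone, and 6 lower and 1 higher over all entries.

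The fat body list had a median of -0.25 over 16 members, with srp at -2.06, Sdr at -0.48 and CG5966 at -1.05 (-0.26 with normexp and quantile normalization), and its brightest members apolpp and FASN1 at -0.10 and -0.12. It lay 1.45 above the control mean on DIP2 knockdown replicate 2, and -0.63 and -1.37 from it on replicates 1 and 3. Without DIP2 knockdown replicate 2 the median was -0.99, with a camera adjusted p of 0.0223 in limma and a p of 0.270 with an estimated correlation, and Lsp2, Adh and Lsp1alpha fell over all entries, and 9 members adjusted over the list alone.

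Medians of the remaining lists were 0.08 for RNA interference machinery, -0.22 for glia, 0.29 for photoreceptor and eye tissue, -0.68 for muscle, -0.82 for the ring gland, -0.83 for salivary gland genes and -0.31 for the digestive tract. They were -0.02 for heat shock and stress, -0.22 for immune and antiviral genes, -0.04 for apoptosis and JNK signalling, 0.06 for circadian clock genes and 0.06 for sex dosage markers. With DIP2 knockdown replicate 2 left out, photoreceptor and eye tissue had -0.07, muscle -0.48, the ring gland -0.09 and salivary gland genes -0.43. In that fit the digestive tract had -0.20, glia -0.11 and immune genes -0.05. On DIP2 knockdown replicate 2 photoreceptor genes lay 1.07 above and ring gland genes -2.28 from the control mean. Over all entries, TpnC4 of the muscle list and PGRP-SC2 of the immune list were the only list members that passed the threshold.

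**Figure D3:**
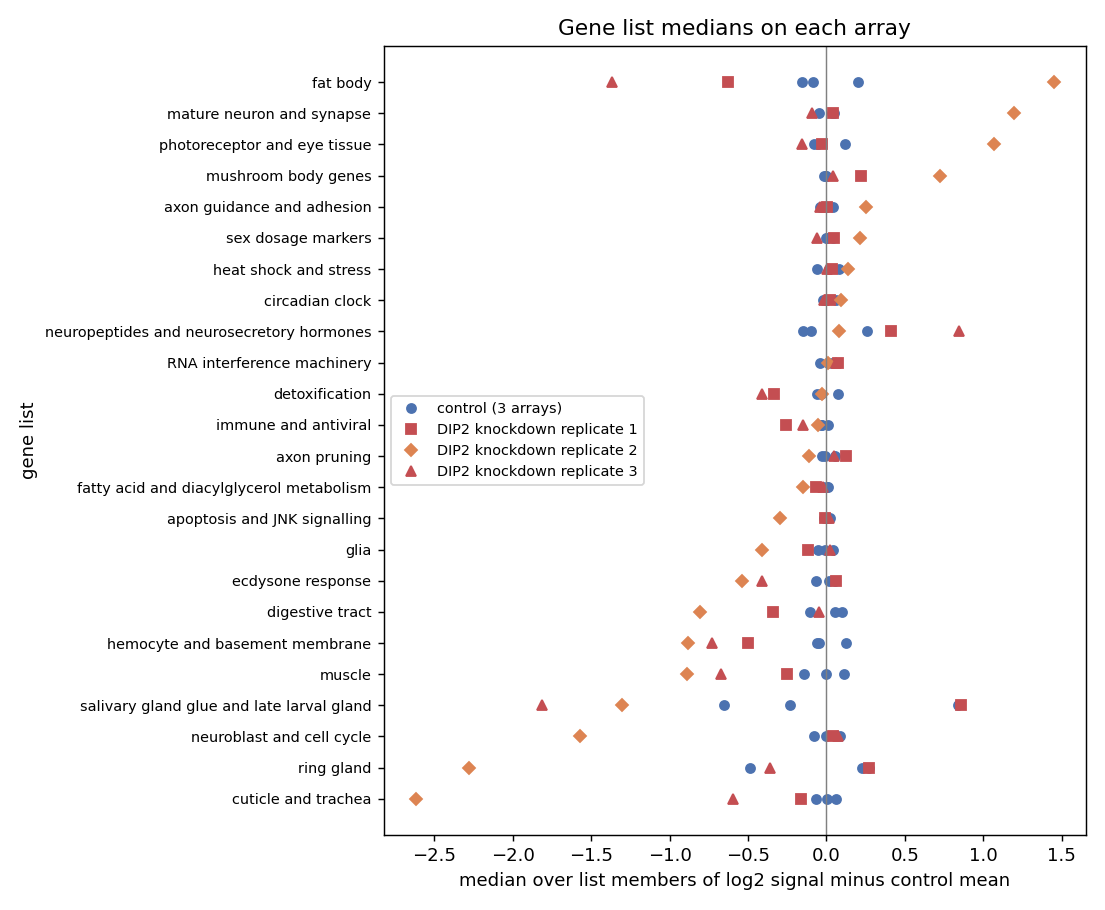
Median over the members of each of the 24 gene lists of log2 signal minus the control mean, per array, ordered by DIP2 knockdown replicate 2. Hemocyte and basement membrane genes lie below the 3 controls on all 3 knockdown arrays. So do, among others, muscle, cuticle and trachea, and immune and antiviral genes, while mushroom body genes lie above the 3 controls. The mature neuron list lies at 1.19 on DIP2 knockdown replicate 2 and near 0 on the other 2.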

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

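The counts of called entries moved with most settings, in limma, from a main 12 higher and 42 lower, and for changes of setting the cause was not tested. Lower calls were 25 with quantile normalization, 13 with median scaling, 21 with normexp and quantile normalization, and 16 with the trend and robust prior. There were 5 higher and 13 lower calls with normexp, 0 and 2 without a filter, and 7 and 23 with probes well above background on all 6 arrays, both of which change the number of entries tested. At an adjusted p under 0.1, limma called 80 and 311. The slide block gave 0 and 3. The replicate block gave 0 and 0, with 2351 entries at an unadjusted p under 0.05, and 2404 with the slide block. Array weights, chosen after seeing the data, gave 77 and 423, and the slide block without DIP2 knockdown replicate 2, chosen likewise, gave 290 and 1358. Leaving out 1 array in turn gave 0 to 319 higher and 0 to 1369 lower, with fewer samples. With control replicate 1, 2 or 3 left out, limma called 0, with 1708, 1353 and 1621 at an unadjusted p under 0.05. It called 0 and 11 without DIP2 knockdown replicate 1, and 1 and 2 without DIP2 knockdown replicate 3. Changes of at least 2-fold numbered 322 with normexp, 299 with normexp and quantile normalization, 1438 without a filter and 423 with the deposited table, and 587 to 1297 with 1 array left out, against 869.

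Same-numbered samples had deviations correlated at 0.267, 0.097 and 0.154, and the numbers were not taken as pairs because the second was just under 0.1. Each array correlated best with its own number, so a pairing stays possible. Median scaling moved the median of all entries by 0.27, and the share of higher calls went from 22.2% to 51.9%, against 39.0% with quantile normalization and 36.4% with normexp and quantile normalization. By that shift alone DIP2 then had 0.083, FASN1 0.14 and apolpp 0.16, above 0, while relative to the median of all entries they stayed at -0.14, -0.08 and -0.06. DIP2 otherwise stayed below 0, at -0.21 to -0.15 with 1 array left out, with an adjusted p in limma of 0.264 to 0.803 over all settings. The gkt value ran from -1.003 (slide block without DIP2 knockdown replicate 2) to -0.58, from -0.95 to -0.69 with 1 array left out, and its adjusted p in limma from 0.028 to 0.429. Ccp84Ad turned to -0.14 with the mean of its probes, -0.021 with array weights, -0.066 with the slide block without DIP2 knockdown replicate 2, and -0.00455 and -0.039 without control replicate 1 and DIP2 knockdown replicate 2, up to 0.261 without DIP2 knockdown replicate 3. The mature neuron median turned to -0.078 with the slide block without DIP2 knockdown replicate 2 and to -0.057 without that array, and was 0.598 without DIP2 knockdown replicate 3. Against 5 lists in the main setting, camera called 2 with array weights, 3 with the slide block without DIP2 knockdown replicate 2, and 3 to 10 with 1 array left out. With an estimated correlation camera called 0 lists, and fry called 0. The hemocyte and neuropeptide lists passed in all 22 other settings at the preset correlation. These settings reuse the same arrays, and at that correlation other splits of the arrays gave as many lists as the real one, so this adds no independent evidence. For the 16 named genes past the threshold, 184 of 343 values stayed past it and 159 did not, all in the same direction. With the other named genes, 61 in all beside DIP2 and gkt, 67 of 1329 values came past it and 7 reversed. Of the 45 not past it, 32 had a value smaller by over 1.5 times or reversed in at least 1 setting. Probes well above background on no array of a group are given as bounds at the main setting, though their values under other settings are fitted ones. Those above it on 1 of 3 are given as fitted differences, which normexp with an offset of 50 made smaller.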

Other observations

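The tests of the repeat-described entries, of chromosome 4, of tissue carry-over without DIP2 knockdown replicate 2, of later stage, of carried-over tissue and of a wrong label in that array, and of roX RNAs were chosen only after the results were seen.

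Some entries described as transposable elements, reverse transcriptases, viral-type polyproteins or ribosomal RNA fell in DIP2 knockdown brains. Of 104 such entries, 9 fell and 0 rose with all 6 arrays, among them reverse transcriptase, R1DM and Pol protein sequences. With DIP2 knockdown replicate 2 left out, 48 fell and 2 rose. This share of falls, 96%, was not shown to differ from the 91.0% among other called entries without a gene name (Fisher exact p = 0.306), and 81.1% of all calls were falls. The largest unnamed fall was in TC241367 on 3L, at least 64.4-fold lower at the main setting. By fitted difference the largest unnamed rise was 5.23 in GH14214 on chromosome 4. GH14214 was well above background on 1 of 3 control arrays, so its size and rank rest partly on signals near background. Both entries were named after their values were seen. Salivary gland genes lay 0.84 and 0.86 above the control mean on control replicate 1 and DIP2 knockdown replicate 1, and between -0.23 and -1.81 on the other 4 arrays.

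Of the 10 splits of the 6 arrays into 3 against 3, the real one gave 54 called entries and the highest of the others 0, so 1 split reached the real count. The filter used the real groups and was not redone for each split, which can favour the real one. The real split gave 30 called entries with probes well above background on all 6 arrays and 2 without a filter. Other splits were not run with those filters. For 2-fold changes the real split gave 869 and the highest of the others 212, again 1 split. For gene lists the real split gave 5 and the highest of the others 10, and all 10 splits gave at least 5, at a preset correlation of 0.01, while estimated correlations of the lists reached 0.70. With 10 splits no share under 0.05 can be reached.

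The called entries may reflect differences between fly stocks as well as DIP2 loss. On chromosome 3, which carries the RNAi transgene by the genotype notation, the odds ratio was 0.863 (95% interval 0.774 to 0.962) without DIP2 knockdown replicate 2, which argues against an excess there, and chromosome 4 had an odds ratio of 1.83 (1.29 to 2.55). With all 6 arrays the odds ratio of chromosome 3 was 1.02 (0.528 to 1.94), too wide to decide. A stock difference in repeats stays open, as does an effect of DIP2 loss on them. Without DIP2 knockdown replicate 2, repeat-described entries had an odds ratio of 6.82 (4.53 to 10.3), and 5.88 with a first word list. That word list was narrowed in steps because it matched unrelated descriptions. In the same fit they had 3.43 (2.27 to 5.17) among entries without a gene name, which as a whole had 3.41 (3.07 to 3.80). With all 6 arrays the odds ratio was 28.7 (12 to 61.7) for repeat-described entries and 4.56 (2.50 to 8.64) for entries without a gene name. Stage and dissection stay open. The ecdysone response list had a median absolute difference of 0.41, against 0.30 for all entries, and 0.28 without DIP2 knockdown replicate 2. At most 4.35% of a tissue list (muscle) was called one way with all 6 arrays. That was TpnC4, which rose while the muscle median was -0.68. Medians of the tissue lists ran from -1.19 (cuticle and trachea) to 0.29 (photoreceptor and eye tissue). Without DIP2 knockdown replicate 2, 28.6% of the cuticle and trachea list was called lower.

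DIP2 knockdown replicate 2 stood apart, and RNA degradation was argued against: among 2276 transcripts the probe nearest the 3' end deviated from the probe nearest the 5' end by a median of 0.048 (0.033 to 0.062). A wrongly labelled control library like the other 3 was argued against as well, at sets of 899 entries, each chosen without the array and without the control held out. Its place between controls (0) and the other 2 knockdown arrays (1) was at least 0.631 (0.569 to 0.691), against at most 0.156 for a held-out control. On this array 48.1% to 53.2% of those entries lay nearer the other 2 knockdown arrays, against 1.67% to 7.01% on the held-out controls. A control library that also differed in stage or tissue stays open. At a separate set of 899 entries, called at 2-fold or more between the other arrays, 49.4% (46.1% to 52.7%) lay nearer the other 2 knockdown arrays. This was just under the 50% first set as the bound, and the demand that the interval lie under it was added after the value was seen. Of 69 entries changed 4-fold, 73.9% lay nearer them, which goes against such a library. A later stage and carried-over tissue stay open too: the gap between mature neuron and neuroblast lists, 2.72 against at most -0.45 on any other array, had been seen before it was tested, and the mature neuron list lay 1.11 above and the neuroblast list -1.61 from the other 5 arrays while the fat body list lay 2.17 and photoreceptor genes 1.08 above them. No biological explanation from the design was tested, since the array differs from its own group.

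The roX RNAs, which are made in males, were well above background on all 6 arrays although all samples were labelled female. DIP2 knockdown replicate 3 had the lowest roX2, at -2.38 from the mean of the other 5, and the lowest roX1, at -1.46. On the log2 scale, roX1 lay 1.74 to 4.09 above the percentile subtracted from each array. The roX2 signal lay 1.68 to 2.49 above it on the other 5 arrays and -0.42 from it on DIP2 knockdown replicate 3. Males among the pooled animals are a candidate explanation of this signal. The comparison between arrays cannot decide whether males were present, and no sample labelled male was measured beside them. Whether DIP2 knockdown replicate 3 held fewer males is not settled either. Its roX1 gap to the next array was smaller than the range of the other 5, and the biology of roX in DIP2 knockdown was not tested.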
